A study of Homo sapiens with 27 samples.

How the data were processed

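Total RNA of 3 human colorectal cancer cell lines, LIM1215, SW48 and Caco2, was measured on 27 single-colour Affymetrix whole-transcript arrays. Per the labels' protocols, 250 ng of total RNA from cell pellets was turned into sense-strand cDNA, fragmented and labelled with biotin. Each line was sampled in 3 states with 3 arrays each, which makes 9 groups. Parental cells were the untreated line. Resistant cells were those left after 20 cycles of challenge with NK-CD16 cells (natural killer cells that carry an Fc receptor for antibodies) and cetuximab, an antibody against EGFR, at 1 ug per ml in a 10 cm dish. Withdrawal cells were resistant cells grown for 20 further cycles without treatment. The labels do not say whether the replicates came from separate cultures, so every p-value here measures only the spread between these samples.

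The deposited table holds values that were read here as log2 intensities, with a value per probe set and array. Neither the table nor the labels name the unit, the software, the background correction or the normalization, and the base was inferred from the range of the values. The quartiles of the deposited values are alike within a line and differ between lines, so the levels were not compared between lines, and the contrasts between lines compare only the changes within each line. The values were used as deposited. Arrays give no count of molecules, so the number of arrays limits the precision.

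The table has 24351 probe sets, of which 2903 are controls (612 negative, 2197 positive, 63 ERCC spike-in, 23 antigenomic background and 8 other spike-in controls). Of the 21448 transcript probe sets, 17709 were matched to a single gene symbol through their Entrez identifier, 0 to several, and 3739 were not listed in the naming table and were only counted, except in the alternative with all transcript probe sets. For 20 genes with several probe sets, the brightest was used. This left 17687 genes, 17249 of them protein-coding, with no filter on dim genes. A group mean was called near background when it lay under the 95th percentile of the negative controls of its arrays. A fold against such a group is given as a lower bound over that percentile ("at least"). No fold is stated when both groups are near background, and log2 differences of such genes are differences of deposited values only.

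A linear model with a mean per group was fitted to all 27 arrays with limma 3.58.1 (lmFit and eBayes; 18 residual and 4.12 prior degrees of freedom) in R 4.3.3, with version 1.17.8 of the package data.table for reading. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes within each of 15 contrasts: 3 per line, 3 averages over the lines and 3 differences between lines in the change from parental to resistant. A gene was called at an adjusted p under 0.05. Errors given beside changes are standard errors (SE) of that fit for groups of 3 arrays. Their spread per gene is pooled over all 27 arrays, so arrays of another line can raise it. Overlaps between lines were tested with Fisher's exact test, and permutation tests are named where used. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

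For 25 gene lists, limma's camera was run with a preset correlation between genes of 0.01, two-sided and adjusted over the lists within each contrast. An estimated correlation and limma's fry, which tests whether a list moves on balance in 1 direction without comparing it with other genes, were run beside it. That correlation was estimated over all arrays of the fit, so a single array can change it for the contrasts of every line. The lists were ErbB receptors and ligands, MAPK pathway output, HLA class I and class II antigen presentation, NK-activating ligands, NK- and T-inhibitory ligands, type I interferon response, interferon gamma response, NF-kappaB and inflammatory cytokines, death receptors and granzyme defence, epithelial junctions, mesenchymal transition, integrins and surface adhesion, enterocyte differentiation, goblet differentiation, WNT targets and stem cells, cell cycle, cholesterol synthesis, unfolded protein and amino acid stress, hypoxia and glycolysis, p53 targets, NRF2 and oxidative stress, cancer-testis antigens, NK cell markers, and ribosomal proteins. A further pair of marker lists (B cell and myeloid markers, and epithelial interferon-inducible genes) was used in the closing section and not tested with camera. Several listed genes, ERBB2 and AREG among them, were not on the array or had no name in the table and are not reported here.

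The samples, contrasts, lists, other settings to try and the rule for naming genes were fixed before the data were examined. Named are the 10 genes with the largest change in each direction for each line's change from parental to resistant, and the 5 for its other contrasts, among called genes whose 3 arrays all lay beyond the 3 of the other group. For averages, the 10 in each direction among called genes with the same sign in the 3 lines qualified, and for differences between lines the 5 largest per pair. From each list up to 4 called members with the largest changes are named, and 13 genes were fixed by name (EGFR, ICAM1, B2M, HLA-E, MICA, MICB, PVR, NECTIN2, NCR3LG1, CD58, FAS, SERPINB9 and CD274). Members of near-identical families, such as the HLA and MIC genes, may share probe signal, so which member changed is uncertain.

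The procedure was tested on simulated data for the LIM1215 contrast of resistant with parental cells, on 17687 genes in 10 draws with 200 changed genes each. It recovered 11.6% of genes changed by 0.5 log2, 74.9% of those changed by 1 and 98.3% of those changed by 2, and 6.11% of its calls were false. Of 250 unchanged lists 0 were called, and a list of 20 genes shifted by 0.5 was called in 10 of 10 draws. The simulated genes varied independently, so false calls of lists whose genes are correlated were not tested.

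The alternatives tried were quantile normalization over all arrays, median centring, a trended and robust eBayes, the mean of a gene's probe sets, all transcript probe sets, a filter on dim genes (at least 7.118 on 3 arrays, 10700 genes kept), array weights, a minimum of 2-fold, an adjusted p under 0.01, fits on the 9 arrays of a line or the 6 arrays of a contrast, replicate number as a block, and leaving out each replicate in turn. Added after seeing the data were list tests without replicate 3 of the LIM1215 parental group, averages without the NK cell marker genes, and overlaps without shared genes that were near background in every parental group.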

Results

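Gene expression was measured in the colorectal cancer lines LIM1215, SW48 and Caco2 before, during and after long exposure to natural killer (NK) cells and cetuximab, an antibody that binds EGFR and marks a cell for killing through the NK cell's Fc receptor CD16. The 27 arrays fall into 9 groups of 3: parental, resistant and withdrawal cells of each line. The labels pose the questions of what changed in cells that survived the challenge, and of what stayed changed after the challenge ended. The median deposited value of the genes was 7.904 to 8.052 on LIM1215 arrays, 6.432 to 6.542 on SW48 arrays and 6.989 to 7.081 on Caco2 arrays. Between 43.44% and 53.5% of genes lay above the 95th percentile of an array's negative controls. Positive controls separated from negative controls with an area under the curve of 0.9774 to 0.9861.

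Pearson's r across all genes, which are not independent replicates, was 0.99465 to 0.99646 between replicates in 8 of the 9 groups and 0.84416 to 0.89418 between different lines. In the LIM1215 parental group replicates 1 and 2 had r = 0.99682, while replicate 3 had r = 0.98709 and 0.98721 with them and 0.99169 to 0.99225 with the withdrawal arrays. IFIT1, an antiviral gene induced by interferon, read 13.16 in that replicate and 6.17 and 6.82 in the other two. ISG15, a ubiquitin-like interferon product, read 11.53 there against 7.44 and 7.81. The main comparisons with LIM1215 parental cells are therefore also given without this replicate.

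**Figure D1:**
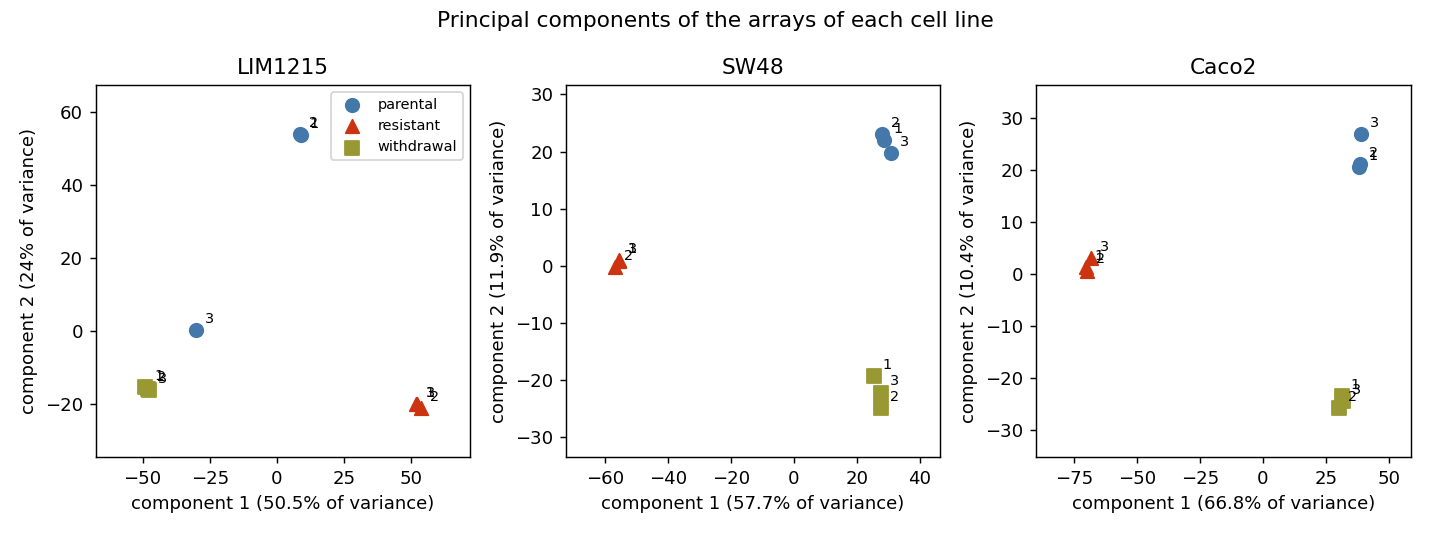
Principal components of the 9 arrays of each line, 1 point per array, with the share of variance on each axis (component 1: 50.5% in LIM1215, 57.7% in SW48 and 66.8% in Caco2). LIM1215 parental replicate 3 lies apart from the other two parental arrays of its line.

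EGFR, the target of cetuximab, fell in resistant SW48 and Caco2 cells and did not pass in LIM1215. In SW48 its level was 13.56 ± 0.166 in parental, 11.3 ± 0.163 in resistant and 13.29 ± 0.0171 in withdrawal cells (SD, n = 3), a change of -2.26 log2 from parental to resistant (SE 0.136, adjusted p = 1.29e-11). In Caco2 the levels were 9.757 ± 0.208, 8.57 ± 0.175 and 9.737 ± 0.167, a change of -1.19 (SE 0.136, adjusted p = 3.46e-07). LIM1215 read 11.53 ± 0.0495, 11.4 ± 0.2 and 11.69 ± 0.117, with a change of -0.13 (SE 0.136, adjusted p = 0.67). After withdrawal, EGFR differed from parental cells by 0.16 in LIM1215, -0.27 in SW48 and -0.02 in Caco2, with adjusted p of 0.483, 0.353 and 0.978. The change from parental to resistant was 2.13 higher in LIM1215 than in SW48 (SE 0.192) and 1.06 higher than in Caco2. Between SW48 and Caco2 it differed by -1.07.

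**Figure D2:**
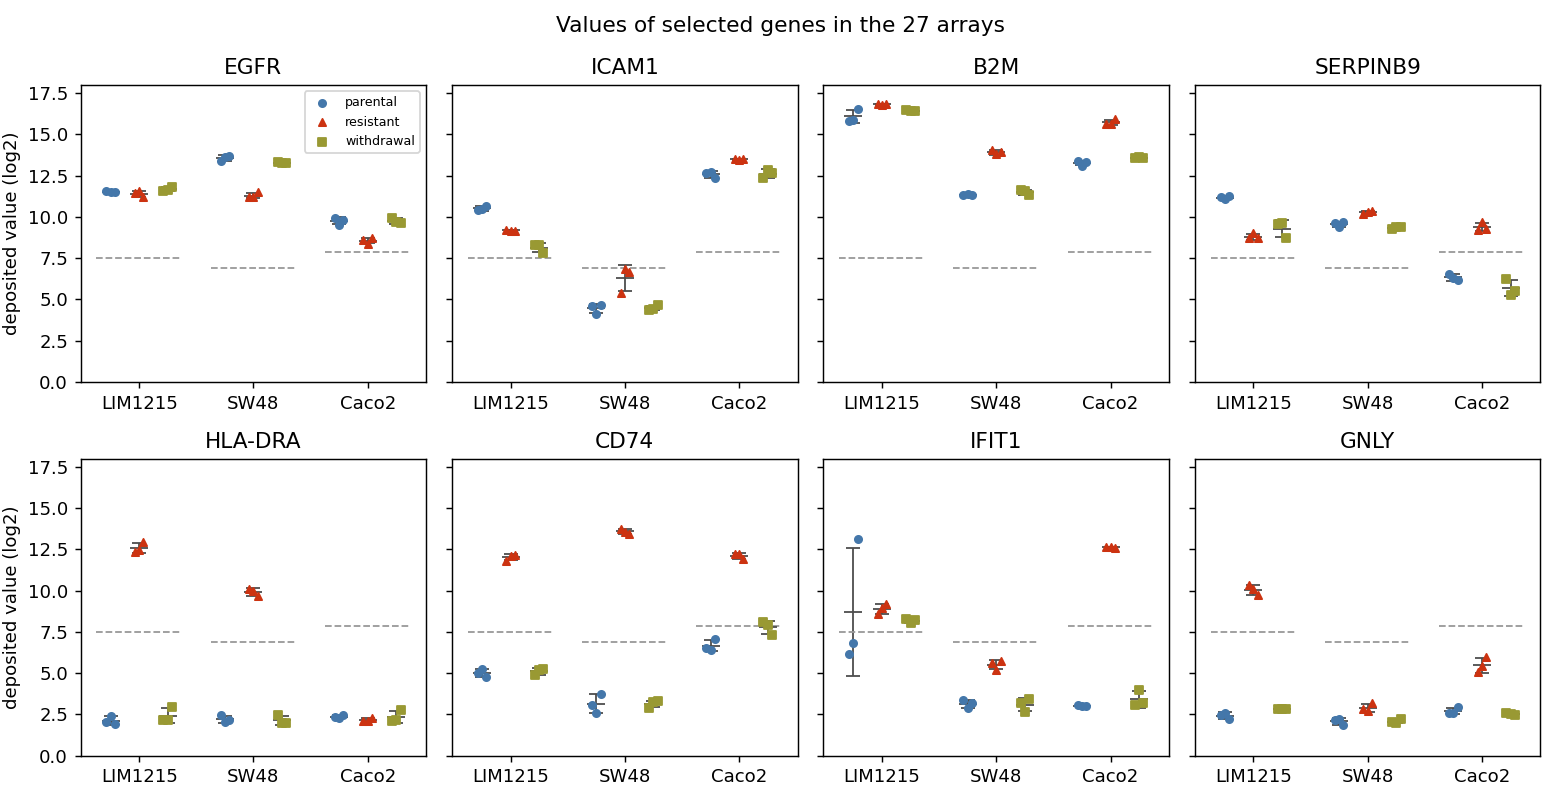
Deposited log2 values of EGFR, ICAM1, B2M, SERPINB9, HLA-DRA, CD74, IFIT1 and GNLY, 1 point per array with the group mean and SD. The dashed line is the mean 95th percentile of the line's negative controls. The mean of CD74 is above it in the resistant group of each line and in no other group, and EGFR is lower in resistant than in parental SW48 and Caco2 cells.

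Antigen-presentation and NK cell transcripts were higher in resistant than in parental LIM1215 arrays, and MAPK output genes were lower. HLA-DRA, the alpha chain of the surface molecule that shows antigens to helper T cells, rose by 10.47 log2 (SE 0.219, n = 3 per group), from near background to at least 37.7-fold above it. GNLY, a pore-forming protein of cytotoxic lymphocytes, rose by 7.63 (SE 0.187, at least 6.51-fold). PHLDA1, a feedback gene downstream of EGFR and MAPK signalling, fell by 3.20 (SE 0.154). Of the 17687 genes, 1913 passed, 959 higher and 954 lower, and 917 of them by 2-fold or more. For 4185 genes (23.7%) the 3 resistant arrays lay entirely above or below the 3 parental ones, against 10% by chance. Without parental replicate 3, 2603 genes passed (1300 higher, 1303 lower), 1609 of them shared with the fit on all arrays.

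The 10 largest rises in LIM1215 also held PIGR, which carries antibodies across epithelia (8.16, SE 0.244, at least 51.8-fold), and the leukocyte actin bundler LCP1 (7.64, SE 0.253, at least 18.4-fold). ALOX5AP, needed for leukotriene synthesis, rose by 7.20 (SE 0.211) and the inflammatory protease gene CASP1 by 7.15 (SE 0.174). CARD16, an inhibitor of that protease, rose by 6.70 (SE 0.322). The class II chaperone CD74 rose by 7.02 (SE 0.237), the chemokine CCL3 by 6.87 (SE 0.202) and the granzyme GZMK by 6.87 (SE 0.263). Among the largest falls were the kallikrein proteases KLK7 (-5.76, SE 0.406) and KLK10 (-4.95, SE 0.213) and TGFBI, a matrix protein induced by TGF-beta (-5.73, SE 0.188, at least 18.1-fold lower). Also lower were the membrane protein TM4SF1 (-5.00, SE 0.255, at least 21-fold), the WNT antagonist DKK1 (-4.40, SE 0.269), PMEPA1, a brake on TGF-beta signalling (-4.30, SE 0.33), and the tight-junction gene CLDN2 (-4.25, SE 0.244). CTSE, a protease of gastric-type epithelium, changed by -4.42 (SE 0.627), or by -3.05 (SE 0.269) without parental replicate 3, and KLK7 then fell by 4.97. The calcium-binding TESC fell by 3.91 (SE 0.273), and RNF212 was near background in both groups.

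All the antigen-presentation groups moved upward in LIM1215. Of 16 measured HLA class I presentation genes 13 rose, 0 fell and 3 did not pass (14 rose when adjusted over the list alone), with a median of 1.52. The immunoproteasome subunits PSMB9 (3.40) and PSMB10 (2.40), HLA-F (2.31) and the peptide trimmer ERAP2 (2.26) led, and B2M, the constant chain of class I, rose by 0.73 (SE 0.146). Of 10 class II genes 9 rose (9 over the list alone; median 3.4), with HLA-DPA1 at 6.01 and HLA-DPB1 at 5.39. Of 19 interferon gamma response genes 12 rose and 1 fell (13 and 1 adjusted over the list alone; median 1.69), led by the guanylate-binding proteins GBP4 (5.51), GBP1 (4.44) and GBP2 (3.68). The camera adjusted p was 4.65e-18, 4.31e-28 and 4.03e-16 for these 3 lists, and 0.000507, 1.44e-08 and 0.00515 with an estimated correlation. Type I interferon genes were higher as a list (median 0.669, adjusted p = 0.000141, but 0.464 with an estimated correlation), with 7 of 34 higher and 1 lower (9 and 2 adjusted over the list alone). XAF1 rose by 5.04, BST2 by 4.73, IFI27 by 3.93 and UBE2L6 by 3.46.

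Parental replicate 3 decided much of that interferon result. Without it 28 of the 34 type I genes rose and 1 fell, with a median of 1.95 and an adjusted p of 4.12e-09 with the estimated correlation. XAF1 then rose by 7.19 (SE 0.255), BST2 by 5.94, IFI27 by 6.23, UBE2L6 by 4.85 and IFIT1 by 2.40 (0.18 and not passing with all arrays). PSMB9 then rose by 4.20 and HLA-F by 2.95.

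Of 23 measured NK cell markers 19 rose in resistant LIM1215 arrays (21 adjusted over the list alone), 0 fell and 4 did not pass (median 2.99, adjusted p = 1.11e-38, 1.44e-08 with an estimated correlation). The chemokine CCL5 rose by 6.61 (8.09 without parental replicate 3), the leukocyte phosphatase PTPRC (CD45) by 5.68 and the protease GZMA by 5.33. CCL5 and the receptor chain IL2RG were also high in untreated parental replicate 3. They read 8.657 and 9.88 there, against at most 4.434 and 7.281 in the other parental arrays, and IL2RG averaged 10.08 in withdrawal arrays. Their rise alone therefore does not point to NK cells. In resistant arrays 10 of the 23 markers were above background, against 1 in parental arrays, and 0 of the 23 are members of another list. With values under background set to it, the list's median change was 0, against 1.3 for class I, 1.28 for class II and -1.05 for MAPK output. It was 0.58 for type I interferon, 0.248 for interferon gamma and 0.00217 for inhibitory ligands. Other measures of NK cell content, such as a sort of the cells, are not given in the sources used here.

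MAPK pathway output, the set of genes that report ERK activity, fell in resistant LIM1215 cells: 12 of 16 fell, 0 rose and 4 did not pass (0 rose and 13 fell adjusted over the list alone; median -1.38, adjusted p = 3.99e-16, 0.018 with an estimated correlation). Without parental replicate 3 the median was -0.834, with 1 higher and 10 lower. The largest falls after PHLDA1 were FOSL1, an AP-1 factor (-2.75), the ERK phosphatase DUSP4 (-2.72) and the transcription factor ETV5 (-2.23, or -1.33 without parental replicate 3). Death receptor and granzyme defence genes were lower (1 higher and 6 lower of 21, adjusted p = 0.0112, 0.018 estimated), with SERPINB9, the inhibitor of granzyme B, at -2.38 (SE 0.217) and the survival gene BCL2 at 2.69. p53 targets were lower (0 higher and 4 lower of 13, adjusted p = 0.0075, 0.018 estimated), including GDF15 (-1.07), PHLDA3 (-0.88) and CDKN1A (-0.80, adjusted p = 0.0653 without parental replicate 3). NK- and T-inhibitory ligands were higher (6 of 14, 1 lower, adjusted p = 0.0135, 0.0916 with an estimated correlation and 0.00496 with it when parental replicate 3 was left out). The immune checkpoint gene CD274 (PD-L1) rose by 1.13 (SE 0.296, adjusted p = 0.0124) but by 0.76 (SE 0.285, adjusted p = 0.081) without parental replicate 3, and did not pass in 3 of 9 alternatives (adjusted p 0.00146 to 0.0882). The unfolded protein and amino acid stress list was lower (0 higher and 3 lower of 17, adjusted p = 0.02, 0.464 estimated), but without that replicate it turned upward and did not pass (3 higher and 0 lower, median 0.0304, adjusted p = 0.309). Without it the cell cycle list was lower (3 of 22 lower, median -0.206, adjusted p = 0.0271), where with all arrays 0 of 22 passed.

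Ligands of NK cell receptors moved both ways in LIM1215, with 3 of 19 higher and 6 lower (median -0.136, adjusted p = 0.249). MICB, a ligand of the activating receptor NKG2D, rose by 2.26 (SE 0.199), while the ULBP2 ligand of the same receptor fell by 2.60 and PVR, a ligand of DNAM-1, fell by 0.73 (SE 0.13). ICAM1, through which lymphocytes grip a target, fell by 1.33 (SE 0.25), and HLA-E, which signals to an inhibitory receptor, rose by 1.48 (SE 0.242). MICA (-0.49, adjusted p = 0.0626), NECTIN2 (-0.01), NCR3LG1 (0.00), CD58 (-0.14) and FAS (-0.04) did not pass. ErbB receptors and ligands had 0 higher and 3 lower of 9 (adjusted p = 0.084), and integrins 1 higher and 3 lower of 15 (adjusted p = 0.0503). Epithelial junctions (0 and 2 of 20), mesenchymal genes (1 and 4 of 19), NF-kappaB genes (2 and 4 of 19), enterocyte genes (4 and 2 of 19), goblet genes (2 and 4 of 14), WNT targets (3 and 3 of 17), cholesterol synthesis (0 and 2 of 15), hypoxia (1 and 3 of 15), NRF2 targets (2 and 3 of 13), cancer-testis antigens (0 and 1 of 14) and ribosomal proteins (0 and 0 of 8) were not called as lists. For enterocyte genes the median was -0.0142 and the mean 0.25, opposite in sign.

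Antigen-presentation genes rose in resistant SW48 cells. CD74 rose by 10.44 log2 (SE 0.237, n = 3 per group), at least 117-fold over background. PTPN13, a phosphatase that restrains death-receptor and growth-factor signals, fell by 8.60 (SE 0.225, at least 31-fold). The amino acid stress list was lower (2 higher and 10 lower of 17; 0.429 with an estimated correlation), with DDIT4, an inhibitor of mTOR, at -2.80. In all, 4014 genes passed (1934 higher, 2080 lower), 1260 of them by 2-fold or more. The arrays of the groups did not overlap for 6279 genes (35.5%, against 10% by chance).

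TNS4, a focal-adhesion protein, rose by 8.20 (SE 0.23, at least 34.1-fold) in SW48, HLA-DRA by 7.71 (SE 0.219), LCP1 by 7.27 (SE 0.253) and the chloride channel ANO1 by 7.19 (SE 0.425, at least 20.2-fold). The protease inhibitor SERPINA1 rose by 7.08 (SE 0.137), the interferon-induced APOL1 by 6.14 (SE 0.288), the basal keratin KRT5 by 5.61 (SE 0.311), the antiviral SAMD9 by 5.36 (SE 0.535) and the kallikrein KLK5 by 5.24 (SE 0.186). Large falls were PSD3, an exchange factor of membrane traffic (-7.84, SE 0.292), the mesenchymal homeobox gene PRRX1 (-6.94, SE 0.255), the matrix protein NPNT (-6.59, SE 0.198) and GRB10, an adaptor that dampens insulin-receptor signals (-5.66, SE 0.341). Others were the chemoattractant receptor CMKLR2 (-5.42, SE 0.27), the nuclear corepressor NRIP1 (-5.13, SE 0.242), the transporter SLCO1B1 (-5.11, SE 0.26), PBDC1 (-5.05, SE 0.146) and the adhesion gene CNTNAP2 (-4.91, SE 0.232).

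In SW48, 13 of 16 class I genes rose and 0 fell (13 over the list alone; median 2.01), with PSMB9 at 4.97, B2M at 2.59 and the peptide-loading gene TAPBP at 2.49. Of 10 class II genes 7 rose (8 over the list alone; median 1.11), including HLA-DRB1 (2.54) and their master regulator CIITA (1.90). Of 19 interferon gamma genes 13 rose (13 and 1 lower adjusted over the list alone; median 1.73), with APOL6 at 4.95 and GBP3 at 4.24. Camera gave adjusted p of 1.57e-14, 9.32e-08 and 1.08e-10, and 0.00157, 0.000449 and 0.0206 with an estimated correlation. Of 34 type I genes 14 rose (15 over the list alone; median 1.43, adjusted p = 7.73e-08, 0.429 estimated), led by SAMD9, IRF9 (4.36), SAMD9L (4.05) and IFI27 (3.98). Of 23 NK cell markers 13 rose and 1 fell (14 and 2 adjusted over the list alone; median 0.828, adjusted p = 2.53e-07, 0.00157 estimated). CCL5 rose by 4.71, GZMA by 4.55, IL2RG by 4.24 and the adhesion molecule NCAM1 (CD56) by 4.14, and 4 markers were above background against 1 in parental cells. Of these genes, CCL5 and IL2RG were also high in the untreated LIM1215 parental replicate 3. PTPRC, which was above background in parental SW48 cells, fell by 1.85. With values under background set to it, medians were 1.66 for class I and 0 for class II, both interferon lists and the NK list.

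The amino acid stress list fell in SW48, with 2 higher and 10 lower of 17 (median -0.765, adjusted p = 7.79e-05, 0.429 estimated), including ATF3 (-2.70), the glutathione-degrading CHAC1 (-2.12) and the cystine transporter SLC7A11 (-1.80). p53 targets were higher (9 higher and 2 lower of 13, 10 and 2 adjusted over the list alone; adjusted p = 0.00117, 0.00817 estimated): the death receptor FAS rose by 1.79 (SE 0.164), TP53I3 by 1.16, ZMAT3 by 1.07 and GDF15 by 1.01. Of 8 ribosomal protein genes 3 rose (adjusted p = 0.0343, 0.429 estimated, 0.175 after quantile normalization). ICAM1 differed by 1.81 but was near background in both groups. B2M, HLA-E (1.47), MICB (1.66), NECTIN2 (1.29, SE 0.122), CD58 (0.59, SE 0.205, adjusted p = 0.0404) and SERPINB9 (0.71, adjusted p = 0.0186) rose, though CD58 did not pass in 6 of 9 alternatives (adjusted p 0.00712 to 0.225) and SERPINB9 in 3 of 9 (0.0144 to 0.0808), while PVR (-1.02) and NCR3LG1 (-0.62) fell, and MICA (0.05) and CD274 (0.53) did not pass. Not called as lists were ErbB (1 higher and 3 lower of 9), MAPK output (4 and 4 of 16), NK-activating ligands (4 and 4 of 19), inhibitory ligands (5 and 2 of 14), NF-kappaB (4 and 2 of 19), death receptors (4 and 5 of 21), junctions (3 and 9 of 20), mesenchymal genes (3 and 0 of 19), integrins (6 and 3 of 15), enterocyte (0 and 2 of 19) and goblet genes (2 and 0 of 14). The same held for WNT targets (4 and 3 of 17), cell cycle (4 and 4 of 22), cholesterol synthesis (3 and 1 of 15), hypoxia (4 and 4 of 15), NRF2 (1 and 3 of 13) and cancer-testis antigens (0 and 0 of 14). For NF-kappaB genes the median (-0.00608) and the mean (0.188) differed in sign.

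Interferon gamma and enterocyte genes rose as lists in resistant Caco2 arrays, and type I interferon genes did so with the preset correlation only (0.109 estimated). IFIT1 rose by 9.59 log2 (SE 0.97, n = 3 per group, at least 29.2-fold) and the mitochondrial interferon product IFI6 by 8.83 (SE 0.54, at least 66.2-fold). The SE of IFIT1 includes the spread of the LIM1215 parental arrays, which read 6.17, 6.82 and 13.16. The same applies to XAF1, OAS2 and CCL5 below. APOC3, an apolipoprotein of mature enterocytes, rose by 4.13. VCAN, a large matrix proteoglycan, fell by 8.15 (SE 0.253, at least 57.3-fold). Calls numbered 4842 (2285 higher, 2557 lower), 1951 of them by 2-fold or more, and arrays of the groups did not overlap for 7053 genes (39.9%, against 10% by chance).

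Among the other large rises in Caco2 were CCL3 (7.93, SE 0.202), XAF1 (7.48, SE 0.94), the RNA sensors OAS2 (7.15, SE 1) and OAS1 (6.86, SE 0.475), and the membrane antiviral IFITM1 (7.14, SE 0.229, at least 38.6-fold). APOL1 rose by 7.11 (SE 0.288), CCL5 by 7.08 (SE 0.674) and the complement gene C3 by 7.03 (SE 0.174). The largest falls after VCAN were the receptor subunit GABRA3 (-7.11, SE 0.214), the RNA-binding RBMS3 (-6.69, SE 0.283) and WLS, needed to secrete WNT proteins (-6.46, SE 0.179, at least 13-fold lower). The detoxifying MGST1 (-6.07, SE 0.202), the stress gene NIBAN1 (-5.70, SE 0.392), the collagen-modifying PLOD2 (-5.32, SE 0.289), NCKAP5 (-5.21, SE 0.27), the endocytic receptor LRP2 (-5.06, SE 0.237) and the kinase gene STK32B (-4.98, SE 0.17) fell too.

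Of 34 type I interferon genes 28 rose in Caco2 and 0 fell (28 over the list alone, median 4.47, adjusted p = 5.18e-22, but 0.109 with an estimated correlation). That estimate also includes LIM1215 parental replicate 3. Interferon gamma genes followed with 16 of 19 higher (17 over the list alone; median 3.36, adjusted p = 1.74e-17, 0.00339 estimated), including the chemokine CXCL9 (5.34). In class I, 15 of 16 rose (15 over the list alone; median 2.42, adjusted p = 6.57e-19, 0.000388 estimated), with PSMB9 at 6.76, the peptide transporters TAP1 and TAP2 at 5.99 and 5.33, ERAP2 at 4.91 and B2M at 2.46. In class II only CD74 (5.44) of 10 genes rose, HLA-DRA read -0.21 and did not pass, and the median (-0.0768) and mean (0.529) differed in sign. Of 23 NK cell markers 21 rose (21 over the list alone; median 2.83, adjusted p = 1.39e-21, 2.94e-06 estimated), with PTPRC at 6.80, GZMA at 6.47 and NCAM1 at 5.74, and 8 were above background against 1 in parental cells. With values under background set to it, medians were 1.79 for type I, 0.849 for class I and 0 for interferon gamma, NK and enterocyte genes.

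Enterocyte genes rose in Caco2 (12 of 19, 0 lower, 12 over the list alone; median 1.14, adjusted p = 1.57e-07, 0.000388 estimated): the glucose transporter SLC2A2 by 3.91, the brush-border peptidase ANPEP by 3.55 and APOA4 by 3.42. Inhibitory ligands were higher (5 of 14, adjusted p = 0.00215, 0.0382 estimated), and so were death receptor and granzyme defence genes (8 higher and 1 lower of 21, adjusted p = 0.0133, 0.0368 estimated), with SERPINB9 at 3.06. NF-kappaB genes were higher (8 of 19, adjusted p = 0.00491, 0.28 estimated), with the chemokine CCL20 at 2.79, IL32 at 1.95 and TRAF1 at 1.57. Goblet genes (5 higher and 1 lower of 14, adjusted p = 0.0382, 0.0957 estimated, 0.0565 after quantile normalization) and cholesterol synthesis (8 and 1 of 15, adjusted p = 0.00763, 0.103 estimated; INSIG1 1.71) were higher. Amino acid stress genes were lower (3 and 11 of 17, median -0.957, adjusted p = 0.00314, 0.441 estimated), with SLC7A11 at -4.36, DDIT4 at -3.13, SESN2 at -3.07 and CHAC1 at -2.95, and so were ribosomal proteins (0 and 6 of 8, adjusted p = 0.00984, 0.354 estimated).

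MICB fell by 2.14 in Caco2 and NCR3LG1, the ligand of NKp30, fell by 2.48, while ICAM1 rose by 0.93 (adjusted p = 0.00657) and HLA-E by 2.06. PVR (-0.09), NECTIN2 (-0.17), CD58 (0.05), CD274 (0.41), MICA (-0.11) and FAS (-0.07) did not pass. Not called as lists in Caco2 were ErbB genes (1 higher and 1 lower of 9; median 0.163, mean -0.0055), MAPK output (5 and 8 of 16), NK-activating ligands (3 and 5 of 19), junctions (3 and 4 of 20), mesenchymal genes (5 and 3 of 19), integrins (4 and 2 of 15), WNT targets (5 and 2 of 17), cell cycle (1 and 4 of 22), hypoxia (7 and 3 of 15), p53 targets (3 and 1 of 13), NRF2 (4 and 3 of 13) and cancer-testis antigens (0 and 0 of 14).

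On average over the lines, CD74 (7.63, SE 0.137), LCP1 (6.78, SE 0.146) and the chemokines CCL3 (6.21, SE 0.116) and CCL5 (6.13, SE 0.389) rose most in resistant arrays among genes of equal sign in each line. Average sizes are differences of deposited values and can include values under background, as for CD74, whose mean was under it in each parental group. The NK and T cell receptor CD96 (5.56, SE 0.163), GZMA (5.45, SE 0.19), GZMK (5.42, SE 0.152), the membrane linker MSN (5.20, SE 0.149), PSMB9 (5.04, SE 0.245) and APOL1 (4.96, SE 0.166) followed. PMEPA1 (-3.18, SE 0.191), VCAN (-2.92, SE 0.146), the ephrin EFNB2 (-2.67, SE 0.181) and PRRX1 (-2.67, SE 0.147) fell most, followed by the ubiquitin ligase PELI2 (-2.52), CREB5 (-2.27), SLC7A11 (-2.22), GXYLT2 (-2.20), MATCAP2 (-2.18) and the cAMP phosphodiesterase PDE4D (-2.13). The average passed for 5031 genes (2322 higher, 2709 lower), 155 genes rose in each line and 50 fell in each. Of the 155 risen genes 75 were near background in all 3 parental groups.

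Class I (15 of 16 higher, median 1.96, 15 over the list alone), class II (9 of 10, median 1.82, 9 over the list alone), interferon gamma (17 of 19, median 2.6, 17 over the list alone) and NK cell markers (22 of 23, median 2.83, 22 over the list alone) rose on average and passed with an estimated correlation as well (8.42e-05, 3e-06, 0.000931 and 2.32e-07). Enterocyte genes were also higher (10 higher and 2 lower of 19, adjusted p = 0.00109, 0.0137 estimated), a list called in Caco2 alone (LIM1215 4 and 2, SW48 0 and 2). Type I interferon (28 of 34 higher, median 2.2), inhibitory ligands (7 higher and 2 lower of 14), MAPK output (2 higher and 11 lower of 16, median -0.615), amino acid stress (1 and 13 of 17, median -0.748) and junctions (1 and 9 of 20, median -0.177) passed with the preset correlation only, with 0.145, 0.075, 0.298, 0.256 and 0.256 when it was estimated. Without LIM1215 parental replicate 3 type I interferon (6.18e-10), inhibitory ligands (0.00895) and amino acid stress (2.96e-05, median -0.44) passed with the estimated correlation too, and MAPK output, called in LIM1215 alone, did not (0.0777). The junction list then no longer passed (adjusted p = 0.117), and NF-kappaB genes did with the preset correlation only (adjusted p = 0.0463, 0.0669 estimated). B2M (1.93, SE 0.0843), HLA-E (1.67, SE 0.14), MICB (0.60), NECTIN2 (0.37), FAS (0.56), SERPINB9 (0.47), ICAM1 (0.47) and CD274 (0.69) passed with a positive average, PVR (-0.62) and NCR3LG1 (-1.04) with a negative one, and MICA (-0.18) and CD58 (0.17) did not pass. The lines differed in sign for MICB (-2.14 in Caco2), SERPINB9 (-2.38 in LIM1215, 0.71 in SW48, 3.06 in Caco2) and ICAM1 (-1.33 in LIM1215; 1.81 in SW48, near background in both groups). CD274 was near background in both groups of SW48 and Caco2, and NECTIN2 and FAS rose in SW48 alone.

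LIM1215 and SW48 shared 414 calls in the same direction (217 expected from n1 × n2 / N), LIM1215 and Caco2 586 (262 expected) and SW48 and Caco2 1106 (551 expected). Fisher's exact p, two-sided, for shared higher genes was 4.98e-37, 1.83e-101 and 4.69e-94, and for shared lower genes 2.21e-09, 3.32e-10 and 3.15e-48. Calls in opposite directions numbered 107 and 147, 124 and 184, and 293 and 250 for the same pairs. Across genes, the changes of the lines had r = 0.172, 0.257 and 0.244. Without LIM1215 parental replicate 3 the first pair of lines shared 642 calls and LIM1215 and Caco2 823.

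The changes differed between lines for 3232 genes (LIM1215 against SW48), 3760 (LIM1215 against Caco2) and 4575 (SW48 against Caco2). In deposited values, TNS4 differed by -10.51 (SE 0.325) in the first pair, HLA-DRA by 10.68 (SE 0.31) in the second and PTPRC by -8.65 (SE 0.261) in the third. These sizes include values under background (TNS4 in parental SW48 cells, HLA-DRA in parental LIM1215 cells and both Caco2 groups, PTPRC in resistant SW48 and parental Caco2 cells). Type I interferon genes rose less in LIM1215 than in Caco2 (0 higher and 17 lower of 34, median -2.67, 1 and 22 adjusted over the list alone; 0.212 with an estimated correlation). Without LIM1215 parental replicate 3 the median was -1.23 and that adjusted p 5.11e-05.

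After withdrawal, class II genes and NK cell markers of LIM1215 cells no longer differed as lists from parental cells, and stress and MAPK genes lay above the parental level. With an estimated correlation the latter pair did not pass on all arrays (0.325 each), but did without parental replicate 3 (1.37e-06 and 0.00365). HLA-DRA fell by 10.16 log2 from resistant to withdrawal cells (SE 0.219, at least 34.9-fold, n = 3 per group), and its difference from parental cells was 0.31. DDIT3 (CHOP), a transcription factor of the stress response, was 3.70 above parental cells (at least 5.89-fold, or 4.82 without parental replicate 3) and DDIT4 3.26 (4.74 without it). ETV5 was 3.01 above parental (3.91 without it). Between withdrawal and parental cells 3724 genes passed (1749 higher, 1975 lower; 1068 by 2-fold or more), and 5019 without parental replicate 3, of which 3483 were shared. Without parental replicate 1 or 2 the count was 2304 or 2260. Arrays of the groups did not overlap for 5588 genes (31.6%, against 10% by chance).

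The largest rises over parental LIM1215 cells were HAND1, a developmental transcription factor (6.15, SE 0.272, at least 25.7-fold), IGFBP1, which binds insulin-like growth factors (5.98, SE 0.881), the collagenase MMP1 (5.21, SE 0.478), PNPLA1 (4.16, SE 0.579) and the amino acid transporter SLC43A1 (3.77, SE 0.579). Without parental replicate 3 these read 7.92 for IGFBP1, 6.19 for MMP1, 5.38 for PNPLA1 and 5.09 for SLC43A1. The glutamate transporter SLC1A3 (-4.72, SE 0.387, at least 19.6-fold lower), GPRC5B (-3.96, SE 0.327), PCP4 (-3.69, SE 0.465) and the prostaglandin receptor PTGDR (-3.64, SE 0.709) were lowest, and read -5.43 (SLC1A3), -4.52 (PCP4) and -5.27 (PTGDR) without it. RNF212 was near background in both groups. In the stress list 14 of 17 genes were higher (14 and 1 lower adjusted over the list alone; median 1.25, adjusted p = 4.8e-09, 0.325 estimated), with the chaperone DNAJB9 and ATF3 at 1.93 each. MAPK output was higher (8 of 16, 9 over the list alone; median 0.534, adjusted p = 4.41e-05, 0.325 estimated), with DUSP5 at 2.37, EPHA2 at 1.20 and PHLDA1 at 1.16, and so were the EGFR ligands HBEGF (3.01, or 4.22 without parental replicate 3) and EREG (1.50, or 2.17) in the ErbB list (2 of 9, adjusted p = 0.0461, 0.325 estimated).

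Cell cycle genes were lower in LIM1215 withdrawal than in parental cells (0 higher and 14 lower of 22, 17 over the list alone; median -0.525, adjusted p = 7.78e-08, 0.325 estimated), with the proliferation marker MKI67 at -1.39, E2F1 at -1.26 and the replication helicase genes MCM6 and MCM2 at -0.99 each. Cholesterol synthesis (0 and 8 of 15, adjusted p = 0.000413, 0.0805 estimated; LSS -1.06) and WNT targets (2 and 7 of 17, adjusted p = 0.00555, 0.0621 estimated; the niche gene SMOC2 -2.21, LEF1 -1.54 and the stem cell receptor LGR5 -1.52) were lower, and junctions (5 of 20, adjusted p = 0.0324, 0.325 estimated) higher. None of the 7 called lists passed with an estimated correlation on all arrays. NK cell markers did not differ as a list (1 higher and 1 lower of 23, adjusted p = 0.797). Without parental replicate 3, 13 lists passed, among them type I interferon (17 higher and 3 lower of 34, median 0.699, adjusted p = 5.15e-06, where all arrays gave 0 and 4), interferon gamma (median 0.617), class I (median 0.252, adjusted p = 0.0213, 0.0603 estimated), NF-kappaB (0.356), integrins (0.303, 0.0646 estimated) and hypoxia genes (0.248). With an estimated correlation 9 of these 13 passed: stress (1.37e-06), cell cycle (2.78e-06, 20 of 22 lower, median -0.804), type I interferon (0.000926), MAPK output (0.00365), junctions, interferon gamma and NF-kappaB (0.0176 each), hypoxia (0.0293) and ErbB genes (0.0357). ICAM1 (-2.40), SERPINB9 (-1.87), NCR3LG1 (-1.28) and FAS (-0.66) were below parental cells, and HLA-E (0.97, or 1.48 without parental replicate 3), PVR (0.86), CD58 (0.78) and the NKG2D ligand ULBP1 (3.68, or 4.97 without parental replicate 3) above. B2M did not pass (0.34), but did without that replicate (0.57, adjusted p = 0.000631). HLA-E did not pass without parental replicate 1 or 2 (highest adjusted p 0.0623), nor CD58 without replicate 1 (0.0556) or FAS without replicate 2 (0.0647).

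SW48 withdrawal cells differed from parental cells in 722 genes (315 higher, 407 lower; 177 by 2-fold or more), and in 1099 when LIM1215 parental replicate 3 was left out of the joint fit, which pools the spread over lines. Leaving out 1 array of its own groups gave 448 to 580. The glucose transporter SLC2A3 was 4.49 higher (SE 0.425, at least 5.2-fold, n = 3 per group), the desmosomal cadherin DSG3 3.39 (SE 0.257), the mesenchymal cadherin CDH11 2.58 (SE 0.235) and the transporter SLC16A4 2.45 (SE 0.479). The aldehyde dehydrogenase ALDH3A1 (-5.68, SE 0.247, at least 13.8-fold), the amino acid transporter SLC6A20 (-3.22, SE 0.338), the epithelial factor ELF5 (-3.15, SE 0.224) and the amine oxidase MAOB (-2.68, SE 0.354) were lower. TNS4 and SMPDL3B were near background in both groups. Of the 13 fixed genes NECTIN2 alone passed (0.65, SE 0.122). By camera 0 of 25 lists passed with the preset or the estimated correlation, 4 by fry, and 2781 genes had an unadjusted p under 0.05. PTPRC was 1.62 above parental cells, and the NK list had 1 of 23 higher.

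In Caco2, 933 genes separated withdrawal from parental cells (483 higher, 450 lower; 316 by 2-fold or more), or 1219 when LIM1215 parental replicate 3 was left out of the joint fit. CD47, the signal that restrains phagocytes, was 4.22 higher (SE 0.224, at least 3.45-fold, n = 3 per group), the complement gene C2 3.47 (SE 0.345), GPR83 3.19 (SE 0.213) and the RNA sensor TLR7 3.08 (SE 0.175). MGST1 (-5.08, SE 0.202, at least 9.02-fold), PSD3 (-4.47, SE 0.292), the ADP receptor P2RY1 (-3.48, SE 0.275) and CDCA7L (-3.42, SE 0.153) were lower, while MID2 and IAH1 were near background in both groups. NRF2 targets, which answer oxidative stress, were the only list to pass (3 of 13 higher, adjusted p = 0.0129, 0.0663 estimated): AKR1C1 1.30, AKR1C2 0.95 and NQO1 0.65. Of the 13 fixed genes NCR3LG1 alone passed (-1.10, SE 0.155). NK cell markers had 0 of 23 higher and 0 lower.

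Averaged over the lines, 2066 genes differed between withdrawal and parental cells (905 higher, 1161 lower), or 3735 without LIM1215 parental replicate 3. PNPLA1 (1.53, SE 0.334), TFAP2C (1.47, SE 0.216), DDIT3 (1.47, SE 0.307), FOSB (1.47, SE 0.312) and the hexokinase HKDC1 (1.42, SE 0.192) were highest, with SLC43A1 (1.39), the drug-metabolising CYP3A5 (1.32, SE 0.184), DDIT4 (1.31, SE 0.37; adjusted p up to 0.0595 without LIM1215 parental replicate 1 or 2), HBEGF (1.30) and TMEM150B (1.27) after them. MGST1 was lowest (-1.90, SE 0.116), then LIMCH1 (-1.61, SE 0.178), TSPAN18 (-1.38), UCHL1 (-1.37, SE 0.119), the adenosine-producing NT5E (-1.35), the drug pump ABCG2 (-1.30), ELF5 (-1.30), the pore-former GSDME (-1.27), RNF212 (-1.27) and CXCL5 (-1.24). Each of the lines moved the same way for these genes, but only 1 gene was higher and 2 lower by call in each line. Cell cycle genes were lower (0 higher and 6 lower of 22, adjusted p = 8.82e-05, 0.621 estimated) and stress genes higher (7 of 17, adjusted p = 1.53e-05, 0.621 estimated), and without LIM1215 parental replicate 3 these were 17 lower and 14 higher, with 1.71e-05 and 3.36e-06 estimated. Both lists were called in LIM1215 alone. MAPK output (9 higher, median 0.236, adjusted p = 9.22e-06, 0.0231 estimated), type I interferon (16 higher and 4 lower, median 0.299, 0.000849 estimated), interferon gamma (median 0.178, 0.043 estimated), NF-kappaB (median 0.194, 0.0194 estimated) and ErbB genes (median 0.0698, 0.131 estimated) passed too without that replicate.

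Withdrawal cells differed from resistant cells by 4942 calls in LIM1215 (2403 higher, 2539 lower), 3920 in SW48 (1955 higher, 1965 lower) and 4364 in Caco2 (2148 higher, 2216 lower). In LIM1215, IGFBP1 rose by 9.28 (SE 0.881), MMP1 by 7.11 (SE 0.478), CTSE by 5.92, TGFBI by 5.86 and SPRR2D by 5.42, while LCP1 (-7.74), PIGR (-7.25), GNLY (-7.24) and CCL3 (-7.20) fell. In SW48, PTPN13 rose by 8.30 (SE 0.225), PRRX1 by 7.64, PSD3 by 7.45, DHRS2 by 6.13 and NPNT by 5.98, while CD74 (-10.45, SE 0.237), HLA-DRA (-7.80), LCP1 (-7.26), ANO1 (-7.12) and APOL1 (-6.01) fell. In Caco2, GABRA3 rose by 9.29 (SE 0.214), VCAN by 7.41, WLS by 5.64, PLPP4 by 5.50 and RBMS3 by 5.23, while IFIT1 (-9.21, SE 0.97), XAF1 (-7.92), IFI6 (-7.68), CCL3 (-7.67) and APOL1 (-7.05) fell. On average NIBAN1 (3.79, SE 0.227), DDIT4 (3.32), GRB10 (3.10), CREB5 (3.08) and PTPN13 (3.02) rose most, and CD74 (-7.22, SE 0.137), LCP1 (-7.00), CCL3 (-6.16), CCL5 (-6.16), GZMA (-5.60), GZMK (-5.45) and CD96 (-5.45) fell most. The size for CD74 includes values under background, as its mean was under it in each withdrawal group.

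From resistant to withdrawal LIM1215 cells 15 of 16 MAPK output genes rose (median 2.25, adjusted p = 1.21e-15, 0.0325 estimated), and 15 of 17 stress genes (median 1.58, adjusted p = 2.91e-10, 0.0782 estimated). NK cell markers fell as a list in LIM1215 (0 higher and 19 lower of 23), SW48 (1 and 12) and Caco2 (0 and 19), and passed with an estimated correlation in each line (2.01e-06, 0.00228 and 2.04e-06). Class I genes fell as well (12, 14 and 15 of 16 lower; 0.0184, 0.00124 and 0.000373 estimated), as did class II genes in LIM1215 and SW48 (9 and 7 of 10 lower; 2.01e-06 and 0.000275 estimated). Enterocyte genes fell in Caco2 (12 of 19 lower, adjusted p = 5e-07, 0.000538 estimated). With the estimated correlation 4 of 15 called lists passed in LIM1215, 5 of 7 in SW48 and 6 of 11 in Caco2. CD274 fell in LIM1215 (-1.48, SE 0.296) and Caco2 (-1.01, SE 0.296, near background in both groups), and HLA-E in LIM1215 (-0.51) passed only without parental replicate 3 of that line (adjusted p = 0.000898).

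Of the genes called in resistant cells, 441 of 1913 (23.1%, 202 expected by chance) were still called in the same direction after withdrawal in LIM1215, 336 of 4014 (8.37%, 82.3 expected; 223 to 318 without 1 array) in SW48 and 556 of 4842 (11.5%, 128 expected) in Caco2. Calls in the opposite direction from resistant to withdrawal cells were made for 1295 (67.7%, 268 expected), 2787 (69.4%, 445 expected) and 3345 (69.1%, 597 expected) of them. The calls that were neither numbered 248, 994 and 1162. In LIM1215 both shares depended on single parental arrays. Without parental replicate 3, 1281 of 2603 calls (49.2%) were still called and 1231 (47.3%) had turned back, while without replicate 1 or 2 the calls still made numbered 291 or 274. Both contrasts of each pair share a group of arrays, so part of an excess may come from that group. Arrays simulated without any change gave r = 0.5 between the first pair of contrasts and -0.5 between the second, with 0 to 0.01 shared calls on average over 100 draws. With no change simulated, hardly any gene could be called at all. That count therefore cannot size the part of the observed excess that comes from a shared group. The observed r across genes was 0.121, 0.29 and 0.343 for the first pair in LIM1215, SW48 and Caco2, and -0.712, -0.872 and -0.901 for the second. The observed covariance exceeded the simulated one by 0.0153, 0.0385 and 0.0787 for the first pair, and the difference was -0.306, -0.346 and -0.56 for the second.

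**Figure D3:**
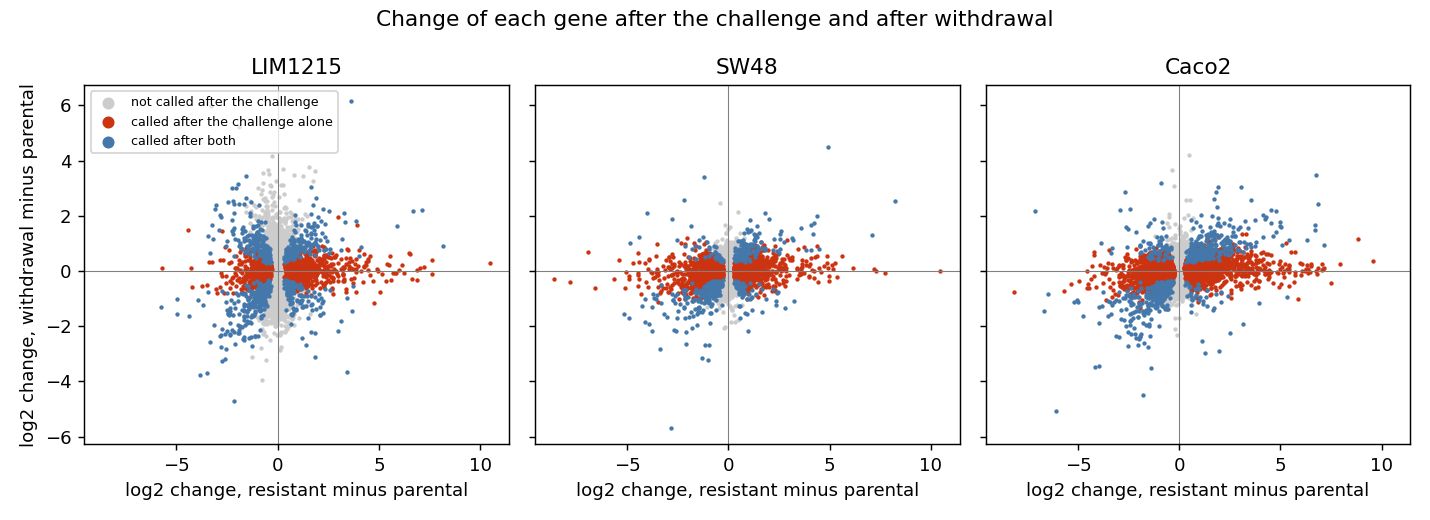
Log2 change from parental to resistant cells (horizontal axis) against that from parental to withdrawal cells (vertical axis), 1 point per gene and 1 panel per line, coloured by the contrasts in which the gene was called. Of the genes called in resistant cells, 23.1% in LIM1215, 8.37% in SW48 and 11.5% in Caco2 were called in the same direction on both axes.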

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

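Of the tests given here, those of NK cell carry-over, of the spread between interferon genes, and, for LIM1215 parental replicate 3, of a mislabelled withdrawal culture, of a mixture for interferon genes and of an interferon response were chosen only after the result was seen.

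NK cell transcripts were higher in resistant than in parental arrays. Of the 23 measured markers 12 rose in all 3 lines (a share of 0.522), and none is a member of another list. Single markers read 12.31 (CCL5), 10.22 (NKG7) and 10.06 (GNLY) in resistant LIM1215 arrays, against 5.703, 5.312 and 2.427 in parental arrays. The parental mean of CCL5 includes replicate 3, which read 8.657. White blood cell genes in general did not rise alike: the median change of 13 B cell and myeloid markers was at most 0.118 of that of the NK markers (0.00135 in LIM1215, 0.0198 in Caco2), with 1, 1 and 2 of them higher in LIM1215, SW48 and Caco2. Under 2 other scalings the markers stayed higher in each line, with a smallest median change of 0.889 (largest adjusted p by camera 7.85e-07). The criterion set beforehand to exclude scaling, a median above 1 in every line, was not met. In SW48 the median was already under 1 with the deposited values, so missing that criterion does not speak for scaling. The outcome set beforehand for scaling as a source, a median under 0.5 in at least 1 line, was not seen. The other scalings moved the median of all genes by at most 0.0608 in these contrasts. These values argue against scaling as the source, though most markers were near background in each line. A criterion based on camera was not among those set beforehand. NK cells left over from the challenge are a candidate source, but their carry-over cannot be told apart from expression by the tumour cells, because each resistant array comes from the challenged cultures, and whether NK cells were removed is not given in the sources used here.

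Type I interferon genes were higher in resistant arrays by camera's preset correlation, but with an estimated one on all arrays the list passed in no line (0.464 in LIM1215, 0.429 in SW48, 0.109 in Caco2). Without LIM1215 parental replicate 3 the list passed by camera with an estimated correlation in LIM1215 (adjusted p = 4.12e-09) and on average over the lines (6.18e-10). RNA of carried-over NK cells may hold such transcripts. If it were the only source, interferon genes and NK markers would differ alike between Caco2 and LIM1215. The excess of interferon genes was 0.458 (two-sided permutation p = 0.155), or -0.181 without LIM1215 parental replicate 3 (p = 0.553), which decides nothing. The spread between interferon genes exceeded that between NK markers by 0.562 (median absolute deviation 1.15 against 0.59, one-sided permutation p = 0.0343; 0.755 and p = 0.0496 without that replicate), too near the threshold to exclude it. An interferon response of the tumour cells stays open as well: at most 0.286 of 7 epithelial interferon-inducible genes rose (2 in Caco2, the complement genes C1R by 4.97 and CFB by 3.11; 1 each in LIM1215, CFB by 4.57, and SW48, IDO1 by 0.60).

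LIM1215 parental replicate 3 lay between the other parental arrays and the withdrawal arrays, at 0.711 of the way (95% interval 0.693 to 0.729 over genes). It thus did not match the withdrawal arrays measured here. The interval covers the genes of this array and not the spread between cultures. A different withdrawal culture under a wrong label is therefore not excluded by it. Lower RNA quality is not seen in the separation of its positive from negative controls, with an area of 0.9835, within 0.9814 to 0.9861 for the line's arrays. On other control measures it lay at the edge of the line's arrays. Its positive control median (13.83) and its 95th percentile of negative controls (7.139) were the lowest. The share of genes above that percentile (53.5%) was the highest. Genes at least 4-fold higher in withdrawal arrays lay farther along (0.798) than those at least 4-fold lower (0.587), a difference of 0.211 (0.182 to 0.24). A mixture of parental and withdrawal RNA would give such a difference. Interferon genes were not left out of these sets, and some lay beyond the withdrawal level, such as IFI27 at 14.65 against a withdrawal mean of 11.72. Part of the difference may come from them. A mixture of RNA like that of the other arrays cannot give the interferon genes, since 34 of 34 lay above every other parental and withdrawal array of the line, by a median of 2.43. That distance is consistent with an interferon response in that culture, where the NK markers were not higher in the median (-0.00286), although CCL5 (8.657 against 4.019 and 4.434) and IL2RG (9.88 against 6.742 and 7.281) were.

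The change from parental to resistant cells was tested for differences between lines, which all of the following results passed. Between LIM1215 and SW48, 3232 genes differed. MAPK output (median difference -1.06), integrins (-0.586) and p53 targets (-1.09) changed more downward in LIM1215, class II (1.76) and NK cell markers (1.3) more upward. By estimated correlation class II (adjusted p = 0.00225), p53 targets (0.000976) and NK markers (0.000976) passed, and MAPK output (0.232) and integrins (0.229) did not. Without LIM1215 parental replicate 3 type I interferon (0.643, adjusted p = 0.00321) and stress genes (0.873) passed too, both also by estimated correlation (0.0168 and 0.000181), as did MAPK output then (0.0441), but not integrins (0.114). With values under background set to it, the median change of NK markers was 0 in both lines, so the size of their median difference rests on values under background. Above background were 10 markers in resistant LIM1215 arrays and 4 in resistant SW48 arrays, against 1 in the parental arrays of each line. Single genes were TNS4 (-10.5), PSD3 (8.73), PTPN13 (8.65), TM4SF1 (-8.16), PIGR (8.01), EGFR (2.13), ICAM1 (-3.14), B2M (-1.85), NECTIN2 (-1.3), FAS (-1.83) and SERPINB9 (-3.09).

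Between LIM1215 and Caco2, 3760 genes differed. Lists changed less or more downward in LIM1215 were MAPK output (-1.27), class I (-1.16), type I interferon (-2.67), interferon gamma (-1.5), NF-kappaB (-0.86), death receptors (-0.489), integrins (-0.671), enterocyte (-1.2), goblet (-1.06), cholesterol (-0.456), hypoxia (-0.436) and p53 genes (-0.489). Class II (2.69) and ribosomal proteins (0.47) went the other way. The calls of MAPK output (0.169), type I (0.212), interferon gamma (0.169), NF-kappaB (0.149), integrins (0.169), hypoxia (0.137) and ribosomal genes (0.256) were lost with an estimated correlation on all arrays. Without LIM1215 parental replicate 3 MAPK output (0.0192), type I (5.11e-05, median -1.23), interferon gamma (0.00916) and NF-kappaB (0.00973, median -0.428) passed with it, and ribosomal genes (0.294) did not. With the preset correlation integrins (adjusted p = 0.0547, median -0.41) and hypoxia (0.205) did not pass without that replicate, and stress genes did (median 1.11, 0.000444 estimated). With values under background set to it, NF-kappaB, enterocyte and goblet genes had medians of 0 in both lines, and class I had 1.3 in LIM1215 against 0.849 in Caco2. Single genes were HLA-DRA (10.7), IFIT1 (-9.41), IFI6 (-8.16), VCAN (7.76), PIGR (7.53), EGFR (1.06), ICAM1 (-2.25), B2M (-1.73), MICB (4.4), PVR (-0.644), NCR3LG1 (2.48) and SERPINB9 (-5.44). IFIT1 rests on that replicate in part, since its change in LIM1215 was 0.18 with it and 2.40 without it.

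Between SW48 and Caco2, 4575 genes differed. Class I (-0.606), type I interferon (-2.29), interferon gamma (-1.49), enterocyte genes (-1.49) and NK cell markers (-1.74) rose less in SW48, and class II (1.09) and ribosomal proteins (0.601) changed more upward. With an estimated correlation class I (0.178), type I (0.394), interferon gamma (0.322) and ribosomal proteins (0.239) did not pass. With values under background set to it, class II, interferon gamma, enterocyte and NK genes had medians of 0 in both lines, and class I had 1.66 in SW48 against 0.849 in Caco2. Single genes were PTPRC (-8.65), ANO1 (8.45), VCAN (7.95), HLA-DRA (7.92), C2 (-7.67), EGFR (-1.07), MICB (3.8), PVR (-0.934), NECTIN2 (1.46), NCR3LG1 (1.86), FAS (1.86) and SERPINB9 (-2.35).

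Among 3739 transcript probe sets with no gene name, used only in the alternative fit on all transcript probe sets, 101 were higher and 106 lower in resistant LIM1215 cells, 274 and 290 in SW48, and 279 and 402 in Caco2.

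Other splits of the arrays were fitted in the same way. The 6 arrays of a contrast within a line make 10 splits, too few for a share under 0.05; the real split alone (1 of 10) gave 778, 620 and 5286 genes in LIM1215 (resistant against parental, withdrawal against parental, withdrawal against resistant), 3242, 209 and 3147 in SW48 and 4124, 605 and 3716 in Caco2, with 0 as the highest of the others each time. For averages, 100 splits within lines were drawn, the real one included. The real split alone (1 of 100) reached the real count each time: 4458 (highest other 3704), 1634 (highest other 1404, which swaps whole groups) and 6068 (highest other 744). A random grouping of these arrays is thus an unlikely source of those counts. The splits speak only of these arrays, since the labels do not say whether replicates came from separate cultures. For differences the real counts were 2351 (highest other 1489), 2834 (3268, a split that swaps whole groups of 1 line, 2 of 100) and 4329 (1916). Splits of this kind remove the changes within each line together with their difference. They therefore cannot decide whether the lines differ by chance.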

How the results depend on the processing

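The list tests without LIM1215 parental replicate 3, the averages without NK cell marker genes and the overlaps without shared risen genes that were near background in every parental group were chosen after seeing the data. Of 605 alternative values of main results 525 kept their direction and their side of the threshold, or stayed within 1.5-fold for counts, 80 did not and 0 reversed. Counts can only stay or move, so a reversal was possible for EGFR values alone. Of 2862 for named genes 2833 were kept, 29 no longer passed and 0 reversed. These genes were chosen from the same data for large changes, or were fixed genes already called, so most were likely to be kept from the start. Those 29 concern CD58 and SERPINB9 in SW48, CD274, HLA-E, CD58, FAS, B2M and MICA in LIM1215, ICAM1 and CD274 in Caco2, and DDIT4 on average. Genes named only as members of a list, such as CDKN1A in LIM1215, were not counted in these alternatives. B2M from resistant to withdrawal LIM1215 cells failed in 7 of 9 alternatives (adjusted p 0.0064 to 0.113). For the results in the next paragraphs the cause was not tested unless it is named.

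With an estimated correlation on all arrays, lists called fell from 7 to 0 (LIM1215, withdrawal against parental), 15 to 4 (LIM1215, withdrawal against resistant), 8 to 5 (SW48, resistant against parental), 12 to 6, 1 to 0 and 11 to 6 (Caco2, resistant against parental, withdrawal against parental, withdrawal against resistant), and 10 to 5, 2 to 0 and 11 to 4 (averages in that order). Fry, which does not compare a list with other genes, called 17, 13, 16, 4, 15, 19, 3, 18, 16 and 5 lists where camera called 10, 7, 8, 0, 7, 12, 1, 11, 10 and 2 (LIM1215 resistant against parental and withdrawal against parental; the 3 contrasts of SW48 and of Caco2; the averages of resistant and of withdrawal against parental). Quantile normalization gave 4 lists rather than 2 for the average of withdrawal against parental cells. Centring gave EGFR in LIM1215 from resistant to withdrawal cells a change of 0.38, which passed, against 0.29. The filter on dim genes gave 4 lists rather than 7 in LIM1215 and 2 rather than 1 in Caco2, withdrawal against parental.

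Array weights, which gave LIM1215 parental replicate 3 a weight of 0.166, raised the calls to 3268 (LIM1215, resistant against parental), 5956 (withdrawal against parental) and 3941 (average, withdrawal against parental). A minimum of 2-fold left fewer genes by its construction: 917, 1068 and 1782 in LIM1215, 1260, 177 and 1211 in SW48, 1951, 316 and 1704 in Caco2, 719, 92 and 787 for averages, 1829, 2276 and 2620 for differences, 159, 288 and 281 for overlaps, and, still called and turned back, 148 and 641 in LIM1215, 89 and 836 in SW48 and 189 and 1342 in Caco2. An adjusted p under 0.01, also stricter by construction, left 1224 and 2201 in LIM1215 (resistant and withdrawal against parental), 307 in SW48, 487 in Caco2 and 894 on average (withdrawal against parental), and 2012 and 2456 for the differences of LIM1215 from SW48 and Caco2.

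Fits on fewer arrays moved some counts. The 9 arrays of a line gave 1230 and 2227 in LIM1215 with 213 still called, and 380 in SW48 (withdrawal against parental) with 193 still called. The 6 arrays of a contrast gave 778 and 620 in LIM1215, and 209 and 605 for withdrawal against parental SW48 and Caco2 cells. Leaving out 1 array of the compared groups at a time gave 1511 to 2603 and 2260 to 5019 calls in LIM1215, 448 to 580 in SW48 and 631 to 710 in Caco2 (withdrawal against parental), and 1451 to 3735 for that average. Overlaps with LIM1215 were 336 to 642 (SW48) and 483 to 823 (Caco2), and genes still called 274 to 1281 in LIM1215, 223 to 318 in SW48 and 379 to 535 in Caco2. The lists called without LIM1215 parental replicate 3 numbered 13 (LIM1215, withdrawal against parental) and 7 (average).

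The paired fit with replicate number as a block moved none of the main counts by more than 1.5-fold, and r between the changes of equally numbered arrays was -0.0407 to 0.0749, so no pairing by number was seen. Without the NK cell marker genes the average of resistant against parental cells called 5007 genes against 5031. Leaving out 23 of 17687 genes could hardly move that count. Without the 75 risen genes near background in every parental group, the overlaps were 339, 511 and 1031. Those 75 were chosen as called higher in each line, so every overlap lost exactly these genes by construction. Neither count can show whether calls or overlaps rest on RNA of carried-over NK cells. Scalings moved the median of all genes by at most 0.1, except centring for LIM1215 minus SW48 (-0.102). Signal over background limits folds, given as lower bounds where a group was near background.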
